A study of Caenorhabditis elegans with 2 samples.

How the data were processed

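The samples were 2 biological replicates of 1 strain of Caenorhabditis elegans (mixed sex, whole young adults, sonicated chromatin, anti-GFP immunoprecipitation of tagged MEL-28). Per the labels, they are separate biological replicates. The files comprised 8 peak lists in narrowPeak layout, with a relaxed list per replicate, a relaxed list from both replicates pooled and a list thresholded for reproducibility (IDR, the irreproducible discovery rate), each on the ce10 and ce11 builds. Per the deposited file manifests, each replicate's list was made from its own alignments and a control that both replicates shared, the pooled list from both alignments and the control, and the reproducible list from these 3 lists. The aligner, the peak caller, its version and the IDR threshold are not given in the sources used here. The control was not analysed here.

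The signal of each peak is the value the authors deposited, with its scale not given in the sources used here. The −log10 q-value of each peak is also the authors' deposited value, and all reproducible ce11 peaks shared one maximum of 2.05, so it could not rank them. Read counts were not analysed here, so the depth per sample is unknown and no interval covers sequencing depth. The replicate lists held 23790 and 19598 peaks on ce11, with median widths of 360 and 484 bp. The pooled list held 17025 peaks and the reproducible list 389, both with a median width of 430 bp. Some intervals were listed more than once with different summits, so the 389 reproducible peaks were 380 distinct intervals, and the 369 nuclear ones 366.

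Coordinates are ce11, 1-based, and were set against the Ensembl release 115 annotation of the same assembly and the matching RefSeq sequence, in which lower case marks repeats. Every ce11 peak ended within its reference chromosome (0 beyond the end). The ce10 lists were used only for counts per chromosome and for overlap among themselves. Mitochondrial peaks stayed out of the enrichment, overlap, signal and sequence tests, and their coverage of the mitochondrial genome is given as a value. The background of the enrichments was the 16528 nuclear peaks of the pooled relaxed list that overlapped no reproducible peak, since these could have passed the threshold. They are weaker by construction, so a second background of the strongest 369 of them was an alternative.

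Replicates were compared by the share of the 389 strongest nuclear peaks that overlapped by at least 50% of the shorter peak, with 1000 circular shifts. A promoter was 1000 bp upstream to 500 bp downstream of the annotated 5′ end of a protein-coding gene. A summit within 500 bp of a gene body counted for a noncoding class. Shares were tested with two-sided Fisher's exact tests and Benjamini-Hochberg adjustment within 10 gene classes, 16 gene lists, 6 chromosomes and 12 motifs, at a threshold of 0.05. Of the listed gene symbols and prefixes, 9 had no match in the annotation. Signal, GC percent and soft-masked percent were tested with permutation tests of 100000 resamples. Exact (Clopper-Pearson) 95% intervals cover counting of peaks only. Neighbouring peaks and overlapping genes are not independent, so p-values describe these lists and not variation between animals.

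The comparisons, gene lists, motifs and the rule for naming genes were fixed before the data were examined. The rule takes the genes at the 20 strongest reproducible peaks, up to 3 members of each list or class with the highest signal, and mel-28 and unc-119. The alternatives were another build, other overlap rules and windows, a stricter set of the reproducible peaks with the higher signal, other backgrounds, and the strongest 389 peaks of each replicate alone in place of the reproducible list.

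The tests of gene classes, gene lists, motifs and promoter share were tested on simulated data, with 200 draws each, and the overlap, chromosome, signal and composition tests were not. With tRNA-associated peaks drawn more often, the tRNA class was called in 100% of draws, and with nothing changed some class of the 10 was called in 3%. For the 16 gene lists the shares were 100% and 2%, for the 12 motifs 100% and 3.5%, and for the promoter share 100% and 4%. The planted effects were about as large as those reported below, with 12 ribosomal genes planted for the gene lists. The 100% therefore does not describe smaller effects or the other lists. Draws with nothing changed were random picks of the weaker peaks or of genes. They cover neither clustered peaks nor differences between strong and weak peaks. The calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6.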

Results

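Chromatin bound by MEL-28 was profiled by ChIP-seq, which sequences the DNA recovered with a protein, in whole young adult Caenorhabditis elegans collected 64 h after synchronisation. MEL-28 is a nuclear pore and kinetochore protein (the worm relative of ELYS). The animals carried a transgene of mel-28 with a C-terminal GFP-FLAG tag, and the immunoprecipitation used an antibody against GFP. The study held 1 group with 2 biological replicates, so no comparison between conditions exists, and the comparisons below set the reproducible peaks against the weaker peaks of the same libraries. The files give peaks and not reads, so the sequencing depth of each library is unknown. The signal value of a peak is the depositors' own and carries no error between replicates. It was used to rank peaks and compare kinds of peak within a list, and across lists only in a correlation of ranks and log2 values between the replicates.

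The reproducible ce11 list held 389 peaks, of which 369 lay on the nuclear chromosomes and 20 on the mitochondrial genome. Nuclear signal values ran from 92.7 to 412 with a median of 114. The 18 strongest peaks of the list were mitochondrial, with values up to 8676, and the first nuclear peak ranked 19. These 389 peaks were the 389 highest by signal among the 17025 peaks of the pooled relaxed list, so the reproducible set is in effect the top of the pooled ranking. The strongest mitochondrial peak (4229 to 5491) had its summit in the coding exon of WBGene00000829, and another strong one (5753 to 6378) had its summit in the coding exon of COX3. Other mitochondrial summits among the 20 strongest peaks lay in ND1, in WBGene00010967, WBGene00010963, WBGene00010965, WBGene00010960, WBGene00010964 and WBGene00010961, in the rRNA genes WBGene00014454 and WBGene00014472, and in the tRNA gene WBGene00014459.

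Because mitochondrial peaks fill 18 of the 20 places in the ranking that was fixed before the data were examined, the 20 strongest nuclear peaks are described as well, a choice made after the values were seen. The strongest (chromosome V, 8500414 to 8500701, signal 412) had its summit 27 bp from the 5′ end of the snoRNA gene ZK994.7, inside an intron of pxn-1. The next (chromosome I, 4172119 to 4172543, signal 367) had its summit in the exon of sls-2.4, which encodes an SL2 spliced leader RNA used in trans-splicing, and of the overlapping ncRNA R12E2.18. A peak on chromosome III (10759123 to 10759367, signal 346) lay 51 bp from the 5′ end of tasp-1. A peak at the snoRNA gene C51F7.4 (chromosome V, 12303514 to 12303744, signal 330) lay in an intron of frm-7. Peaks with signal values of 322 and 305 lay 361 bp from the 5′ end of rpl-15 (chromosome IV, 654814 to 655058) and 287 bp from that of rpl-3 (chromosome III, 3867449 to 3867697), both outside annotated genes. Further down the 20 were tts-1, the snRNA gene sup-6, mdt-26, Y55F3AR.2, mir-52, cox-5A, the snRNA gene R07E5.16, Y17G9B.5 and the snoRNA genes W03C9.9 and T03F7.8. The summit of a peak with signal 251 lay in the exon of rpr-1, the RNA component of RNase P, within an intron of ints-8. One more lay near the ncRNA gene C17C3.23, another near F58G1.11, and another in a coding exon of dos-3 (chromosome III, 835807 to 836067, signal 244), with K02F3.13 the nearest 5′ end. Of these 20 peaks, 4 lay near a snoRNA gene, 5 near an snRNA gene and 0 near a tRNA gene. The peaks named at sup-6 and F58G1.11 overlapped and both lay near sup-6, so the 5 snRNA peaks are not 5 separate loci. All 20 overlapped a peak among the 389 strongest of each replicate's own list, counting mitochondrial peaks in those ranks.

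The first comparison asked how far the 2 replicates shared their strongest peaks. Of the 389 strongest nuclear peaks of replicate 1, 172 (44.2%, exact 95% interval 39.2 to 49.3%) shared at least 50% of the shorter peak with one of the 389 strongest of replicate 2. Circular shifts of the peaks along their chromosomes gave 0.196% on average and 6.94% at most, and the one-sided permutation p of 0.001 is the smallest that 1000 shifts can give. The share was 48% for the 100 strongest, 50% for the 200 strongest, 36% for the 1000 strongest and 29.3% for the 5000 strongest. Anywhere in the list of replicate 2, its top included, 87.4% of the top of replicate 1 had a counterpart, and 88.9% did in the opposite direction. Of the 369 reproducible nuclear peaks, 175 were in the top of both replicates, 175 in the top of 1 and 19 in neither. Across the 366 reproducible peaks that overlapped a peak of both lists by any length, a looser rule than the 50% above, signal in replicate 1 and replicate 2 had a Spearman rho of 0.247 and a Pearson r of 0.383 on the log2 scale. Both permutation p-values were 1e-05, the smallest 100000 resamples can give, and the correlation is across peaks, which are not independent replicates. These peaks are also the top of the ranking by pooled signal of both replicates, a selection that can lower a correlation. Some of them overlap the same replicate peak. The coefficients therefore do not measure agreement over the whole lists.

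**Figure D1:**
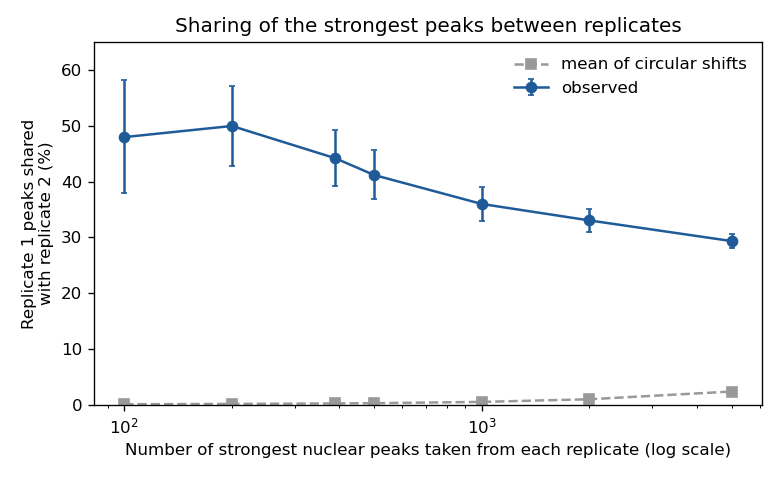
Percent of the strongest nuclear peaks of replicate 1 (vertical axis) that shared at least 50% of the shorter peak with an equal number of the strongest peaks of replicate 2, against the number of peaks taken (log scale). Bars are exact 95% intervals and grey squares are the mean of 1000 circular shifts. The observed share falls from 48% of 100 peaks to 29.3% of 5000.

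Small noncoding RNA genes were the next question, because nuclear pore proteins of this worm have been mapped to genes transcribed by RNA polymerase III. A tRNA gene lay within 500 bp of 53 of the 369 reproducible nuclear summits (14.4%), against 2.31% of the 16528 pooled relaxed peaks that overlapped no reproducible peak (odds ratio 7.09, 95% interval 5.10 to 9.69, Fisher's exact test with Benjamini-Hochberg adjustment over 10 classes, adjusted p = 4.66e-24). For snoRNA genes, whose products guide modification of other RNAs, the shares were 11.1% and 0.944% (odds ratio 13.1, 8.90 to 18.96, adjusted exact p = 1.68e-27). For snRNA genes, which include spliceosomal and spliced leader RNAs, they were 4.34% and 0.327% (odds ratio 13.8, 7.31 to 24.8, adjusted exact p = 4.11e-12). Unclassified ncRNA genes, many of which overlap other genes, were near 27.9% and 10.4% (odds ratio 3.35, adjusted exact p = 5.75e-20). Many of these reproducible summits also lay near a tRNA, snoRNA or snRNA gene. No test left those out, so the ncRNA class is not a separate result. Together, 110 reproducible summits (29.8%) lay near a tRNA, snoRNA or snRNA gene, against 3.55% of the others, and 72 of these 110 lay outside every protein-coding promoter window. Against the strongest peaks outside the reproducible set, only the snoRNA class kept its call, with values given below.

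The peaks covered a minority of each class. A reproducible summit lay near 65 of 612 nuclear tRNA genes, 43 of 346 snoRNA genes and 13 of 129 snRNA genes. The tRNA genes with a peak belonged to 20 of 21 isotypes, led in number by 9 of 42 tRNA-Pro, 7 of 46 tRNA-Lys and 7 of 55 tRNA-Gly genes. The tRNA genes with the highest signal were WBGene00023111 (tRNA-Glu, chromosome X, 3035976 to 3036047) and WBGene00023110 (tRNA-Gly, 3036164 to 3036235), which shared a peak of signal 205, and WBGene00014333 (tRNA-Ala, chromosome X, 9743589 to 9743660) with signal 169. The leading snoRNA genes were ZK994.7, C51F7.4 and C51F7.3, and the leading snRNA genes were sls-2.4, sup-6 and sls-2.2 (signal 255). Among spliced leader genes, 6 of the 18 sls-2 genes and 0 of the 12 sls-1 genes, which encode the SL1 RNA, were within 500 bp of a reproducible summit. The 6 sls-2 genes had 5 distinct peaks. The difference between the families was not tested, and whether reads can be placed uniquely at the sls-1 genes was not examined. The leading ncRNA genes were R12E2.18, tts-1 and F58G1.11. Relative to the annotated 5′ end, the median summit lay at 10 bp for 53 tRNA peaks, -40 bp for 41 snoRNA peaks and 92 bp for 16 snRNA peaks, negative values being upstream. The 16 snRNA peaks fell on 11 genes, 5 of them being second summits, and with the strongest summit of each gene the snRNA median was 78 bp on genes of median length 111 bp.

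**Figure D2:**
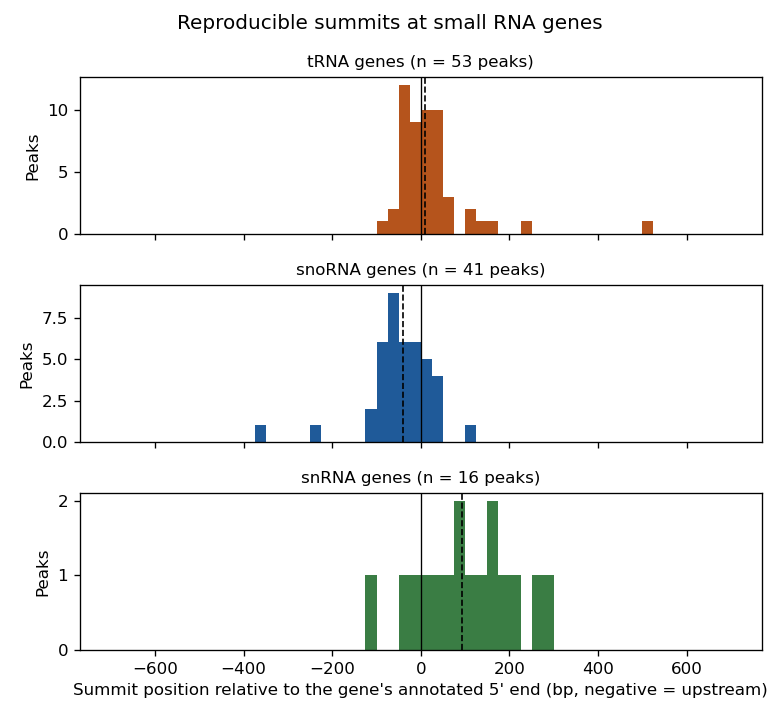
Number of reproducible peaks (vertical axis) by the position of the summit relative to the annotated 5′ end of the nearest tRNA, snoRNA or snRNA gene (horizontal axis, bp, negative upstream). Dashed lines are the medians, 10, -40 and 92 bp, and solid lines mark the 5′ end.

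The tests of lincRNA, antisense RNA, miRNA, piRNA, pseudogene and rRNA classes did not pass the threshold, with adjusted p from 0.263 to 1. The piRNA class passed as less frequent with the strongest peaks of replicate 2 alone (odds ratio 0.429, adjusted exact p = 0.0374). Against circular shifts it passed only just (odds ratio 0.512, adjusted permutation p = 0.04995), and the pseudogene class passed too (odds ratio 0.339, adjusted permutation p = 0.00799). The highest-signal members of these classes were linc-128, linc-84 and linc-2, anr-20 and anr-36, mir-52 and mir-51, the piRNA genes 21ur-14981, 21ur-5229 and 21ur-12279, and the pseudogenes WBGene00044053, WBGene00013638 and WBGene00023344. Some of these peaks lay at other genes. The 21ur-5229 summit lay in the tRNA gene WBGene00022903, that of linc-84 in the snoRNA gene F55H12.9 and that of 21ur-12279 in the 5′ UTR of atp-1. Of the 20 nuclear rRNA genes 0 had a reproducible summit. Only 2 of the 16528 other pooled summits lay near one, so these lists say little about the rRNA class. Against the 369 strongest peaks outside the reproducible set, only the snoRNA class of these 10 classes passed (odds ratio 4.48, adjusted exact p = 7.4e-05). In that comparison the tRNA odds ratio was 1.21 (adjusted exact p = 0.832), the snRNA odds ratio 2.04 (adjusted exact p = 0.483) and the ncRNA odds ratio 1.38 (adjusted exact p = 0.369). Every comparison with the other pooled peaks sets strong against weak peaks of 1 ranking.

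**Figure D3:**
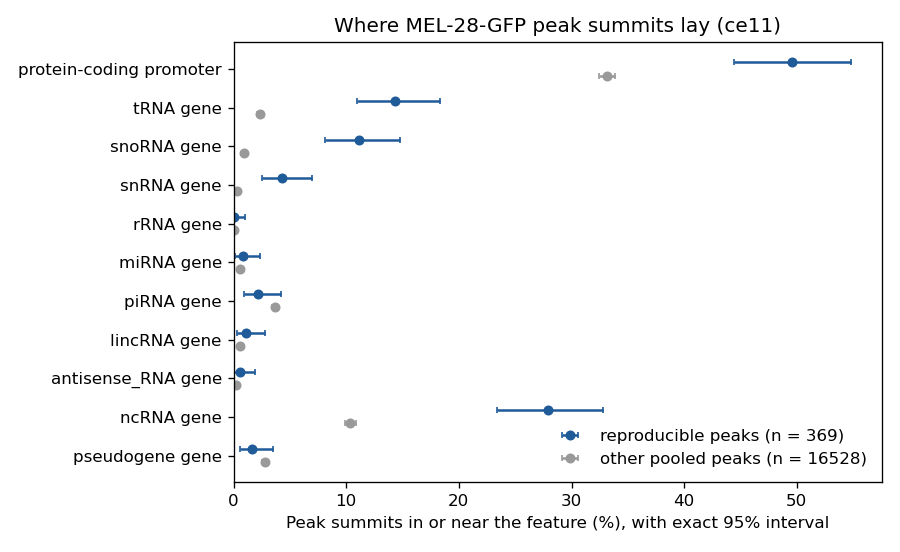
Percent of peak summits (horizontal axis) in a protein-coding promoter window or within 500 bp of a gene of each noncoding class, for the 369 reproducible nuclear peaks (blue) and 16528 other pooled peaks (grey), with exact 95% intervals. The tRNA, snoRNA, snRNA and ncRNA classes and the promoter window were more frequent among reproducible peaks.

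Protein-coding promoters held 183 of the 369 reproducible summits (49.6%, exact 95% interval 44.4 to 54.8%) and 33.1% of the other pooled peaks. The window ran from 1000 bp upstream to 500 bp downstream of an annotated 5′ end (odds ratio 1.99, 1.61 to 2.46, two-sided Fisher's exact test, p = 1.36e-10). Outside promoters, 37 summits lay in exons of protein-coding genes, 65 in their introns and 84 outside protein-coding genes. Noncoding genes were not counted in this split, so some of the 84 lay inside noncoding genes. Exons held 10.0% of reproducible and 21.5% of other summits, and introns 17.6% and 24.9%. Against the 369 strongest peaks outside the reproducible set the promoter odds ratio was 1.11 (exact p = 0.507).

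Ribosomal protein genes and chaperone genes carried reproducible summits in their 5′ windows more often than other protein-coding genes. Of all 19973 protein-coding genes, these lists included, 244 had one. Among ribosomal protein genes 12 of 81 did, against 232 of 19892 others, from 12 distinct peaks (odds ratio 14.7, 7.16 to 27.9, Fisher's exact test, adjusted p = 4.53e-09 over 16 lists). They were 7 large-subunit and 5 small-subunit genes, led by rpl-15 (signal 322), rpl-3 (305) and rpl-20 (244), and every one of the 12 summits lay upstream, from 69 to 438 bp before the 5′ end. Of the 12 peaks, 2 also lay near a snoRNA gene, and 5 lay nearer to the 5′ end of another protein-coding gene: those of rpl-20 (Y17G9B.5), rps-20 (ekl-4), rps-19 (hsr-9), rps-26 (tmem-107) and rps-15 (F36A2.9). Among heat shock and chaperone genes 7 of 60 had a summit, against 237 of 19913 others, from 7 peaks (odds ratio 10.96, 4.16 to 24.5, adjusted exact p = 6.63e-05). The highest among the genes of the list, which was drawn by symbol, were cct-8 (signal 263), a subunit of the cytosolic chaperonin, hsp-60 (208), a mitochondrial chaperonin, and hsp-1 (170), a member of the heat shock protein family. The peaks of cct-8, hsp-60 and hsp-110 lay nearer to the 5′ ends of Y55F3AR.2, Y22D7AL.10 and rpn-3. Those of cct-8, hsp-1, dnj-13 and hsp-110 also lay near an ncRNA gene. The dnj-13 summit was inside the ncRNA gene F54D5.22 and an intron of dhgd-1. The product of Y22D7AL.10 is annotated as a 10 kDa mitochondrial heat shock protein. That gene and F44E5.4, annotated as heat shock protein 70 (signal 181), were outside the list by symbol and counted among the others. With the strongest peaks of replicate 2 alone the chaperone list no longer passed (odds ratio 5.03, adjusted exact p = 0.0893). With genes that had any pooled peak as the background, the odds ratio of the ribosomal list fell to 5.01 (adjusted exact p = 0.000386) and that of the chaperone list to 7.19 (adjusted exact p = 0.00145). The strongest other peaks were not used as a background for the gene lists. Nonspecific recovery of DNA at highly transcribed loci was not tested for them and stays open.

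The remaining 14 lists did not pass in this comparison, and 3 of them passed under an alternative. Among nuclear pore and envelope genes, the class to which mel-28 belongs, 3 of 48 had a summit (adjusted exact p = 0.0832): npp-6 (signal 102, summit in an intron of spd-5), npp-8 (101) and the importin gene imb-3 (92.7). This list passed with a window of 500 bp upstream to 250 bp downstream (odds ratio 7.57, adjusted exact p = 0.0471) and with the strongest peaks of replicate 2 alone (odds ratio 8.74, adjusted exact p = 0.0126). Mitochondrial respiration had 3 of 39 (cox-5A, atp-1 and cox-6A, adjusted exact p = 0.0635), and passed with replicate 2 alone (adjusted exact p = 0.0417). Cell cycle and replication had 2 of 25 (pcn-1 and lin-35) and splicing 2 of 25 (prp-19 and snr-4), each with adjusted exact p = 0.0989. Translation factors had 2 of 38 (eif-3.C and eif-2Bgamma), and passed with replicate 1 alone (odds ratio 11.2, adjusted exact p = 0.000853). The eif-2Bgamma summit lay inside the snRNA gene sup-39, and those of cox-6A and snr-4 also lay near an snRNA gene. Kinetochore genes had 1 of 31 (knl-3), the proteasome 1 of 33 (rpn-3, which shared its peak with hsp-110), germline genes 1 of 40 (ego-1, signal 223) and cuticle genes 1 of 179 (col-85, whose peak lay at a tRNA gene). Histone (81 genes), sperm (50), intestine (25), muscle (31) and neuronal (136) lists had 0 genes with a summit. For these 5 lists the exact upper 95% limits of the share ran from 2.68% to 13.7%.

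Chromosome III held 74 of 369 reproducible and 2479 of 16528 other summits (odds ratio 1.42, adjusted exact p = 0.0297 over 6 chromosomes), and chromosome V held 50 and 3198 (odds ratio 0.653, adjusted exact p = 0.0295). The other 4 chromosomes did not pass. Chromosome III lost its call with the top peaks of either replicate alone (adjusted exact p = 0.201 and 0.657) and among the stronger reproducible peaks (odds ratio 1.10, adjusted exact p = 0.725). It also lost it with the ce10 lists (odds ratio 1.35, adjusted exact p = 0.0807), and chromosome V lost its call with the top peaks of replicate 2 alone (adjusted exact p = 0.105). The X chromosome did not differ detectably from the autosomes (odds ratio 0.947, 0.707 to 1.25, exact p = 0.782). With each autosome divided by length into 3 equal parts, the central part held 33.9% of reproducible and 36.5% of other autosomal summits (odds ratio 0.891, 0.695 to 1.14, exact p = 0.369). That comparison was made because autosome arms lie near the nuclear periphery.

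Within the reproducible list, signal did not differ detectably by promoter position. Its median was 115 at 183 promoter summits and 114 at the other 186 (difference 1.41, two-sided permutation p = 0.598). Near tRNA genes the median was 108 against 116 elsewhere (difference -8.04, permutation p = 0.0968). In replicate 1 alone the promoter difference was 6.75 (permutation p = 0.0215), and in replicate 2 alone it was -2.64 (permutation p = 0.199). As a mean of log2 signal the tRNA difference was -0.16 (permutation p = 0.0103).

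Sequences within 100 bp of reproducible summits were richer in G and C than those of other pooled peaks, at 44.6% ± 7.58 (SD, n = 369 peaks) against 38.8% ± 7.46 (SD, n = 16528 peaks), and had less soft-masked sequence (23.3% ± 21.9 against 28.5% ± 22.5). The permutation p-values were 1e-05, the smallest possible, and 2e-05. Of 12 motifs, 9 differed. The RNA polymerase III B box, a promoter element inside tRNA genes, was found at 22.2% and 9.23% of summits (odds ratio 2.81, adjusted exact p = 2.53e-12), and the A box at 34.4% and 22.4% (odds ratio 1.81). The Sp1-like motif CCGCCC had an odds ratio of 2.98 (adjusted exact p = 1.9e-09), the GAGAGAGA repeat 2.75 (adjusted exact p = 7.48e-06) and the E2F-like motif 1.66. The GATA site (odds ratio 0.51, adjusted exact p = 0.000136), AT-rich, TATA-like and splice acceptor motifs were less frequent. Against the 369 strongest other peaks 0 of the 12 motifs passed, while the GC difference was 2.21 percentage points (permutation p = 8e-05). Among all 2080 6-mers, 324 were more and 189 less frequent after adjustment, led by CGCGCA (19.2% against 4.77% of summits, odds ratio 4.75) and GCGCGC (14.6% against 2.83%).

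No reproducible peak lay within 20 kb of mel-28 (chromosome III, 4786080 to 4792391) or within 10 kb of unc-119 (chromosome III, 10902641 to 10908935), the tagged gene and the marker gene of the strain. The pooled relaxed list had 2 peaks in the mel-28 region, the better ranking 2544, and 3 in the unc-119 region, the best ranking 6747.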

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

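The checks of mitochondrial coverage and of nonspecific recovery were chosen only after the results were seen, and the others in this part were set before their own values were seen. The reproducible list held 20 peaks on the mitochondrial genome, a signal outside the nuclear comparisons. They covered 55.4% of that genome, against 0.147% of the nuclear genome covered by reproducible peaks, and 18 of them ranked above every nuclear peak. Whether mitochondrial DNA was more abundant in the immunoprecipitated libraries than in the control stays open, because the coverage restates the pattern and the control was not analysed here. No biological explanation was tested.

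The excess of tRNA, snoRNA and snRNA genes near reproducible summits was weighed against 3 technical explanations. Stratified by GC percent of the window, the odds ratio for the 3 classes together was 8.80 (95% interval 6.85 to 11.3) where it was 11.5 unstratified, which argues against GC content as the whole cause. Among the 354 reproducible summits whose surrounding 51 bp occur once in the genome, the odds ratio was 11.7 (9.07 to 15.1). This argues against exact copies of the summit sequence as the whole cause. Copies that differ at a base count as different here, and most peaks are wider than 51 bp. Reads shared between near-identical gene copies therefore stay open. The values of 8.80 and 11.7 are both against the weaker pooled peaks. Against the strongest other peaks the snoRNA class alone of the 3 passed (odds ratio 4.48), with 1.21 for tRNA and 2.04 for snRNA genes. Nonspecific recovery of DNA at highly transcribed loci stays open, because 0 untagged libraries were among the samples, and no biological explanation was tested, since the design holds 1 group.

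The excess of the Sp1-like motif, the GAGA repeat and the B box was weighed against GC content. For the B box, nearness to tRNA genes was weighed as well. The other motifs that differed and the 6-mers were not stratified by GC percent, so the part of GC content in them stays open. Stratified by GC percent, the odds ratio was 1.93 (1.41 to 2.64) for the Sp1-like motif, 1.80 (1.22 to 2.64) for the GAGA repeat and 2.34 (1.81 to 3.02) for the B box. Each was lower than without strata but its interval stayed above 1, so GC content may account for part of the excess. The strata were 5 percentage points wide and GC can differ within them, so whether GC content accounts for all of the excess stays open. Away from tRNA genes the B box odds ratio fell from 2.81 to 1.58 (1.09 to 2.23), so tRNA genes account for part of it. Against the strongest other peaks none of these 3 motifs passed the threshold, so what separates strong from weak peaks in general stays open.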

How the results depend on the processing

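The sharing of top peaks between replicates kept its direction and its side of the threshold under all 5 alternatives, from 36% to 45.8%, and the list length was 385 on ce10. With the strongest other peaks as background, run for the promoter, class and sequence results, the promoter odds ratio became 1.11, 1 class and 0 motifs passed in place of 4 and 9, while the GC and soft-masked differences still passed; the B box, Sp1-like and GAGA odds ratios were 1.5, 1.48 and 1.04. That background holds peaks just below the threshold and fewer of them, and the cause was not tested further. The promoter odds ratio stayed past the threshold under the other alternatives, from 1.55 without replicate 1 to 2.82 with circular shifts; thinning clustered summits, chosen after seeing the data, gave 2.01. Circular shifts raised the class odds ratios to 29.2 for tRNA, 31.0 for snoRNA, 37.6 for snRNA and 5.54 for ncRNA genes, and 6 classes passed. Among the stronger reproducible peaks the tRNA odds ratio was 4.58 and the snoRNA odds ratio 20.4, and within 100 bp the latter was 25.4. Without replicate 1, 5 classes passed, and 3 gene lists passed in place of 2 with the narrower window or either replicate left out. The count of chromosomes was 2, and 1 (chromosome V) with the ce10 lists, 3 with chromosome length as background, and ranged from 0 to 1 when either replicate was left out. It was 2 among the stronger reproducible peaks, with chromosome I in place of III. The X odds ratio crossed 1 with the ce10 lists (1.02) and ranged from 0.905 to 1.18 with a replicate left out. The odds ratio of the autosome middle crossed 1 with chromosome length as background (1.02) and ranged from 0.918 to 1.04 with a replicate left out. None of these X and middle values passed a test. The promoter difference in signal was 6.75 in replicate 1 alone and -2.64 in replicate 2 alone, and the tRNA difference passed as a mean log2 value (-0.16). The cause of these changes was not tested. The single classes, lists and chromosomes that passed at first were followed, as were the B box, Sp1-like, GAGA and GATA motifs. The other motifs that passed were not followed singly. Among the values followed, 55 kept their call and 13 lost it, with 0 reversals. No paired analysis was possible because the study holds 1 group. Depth is unknown, so its limit on weak peaks could not be given.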

Other observations

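All tests in this part were chosen after the results were seen. At tRNA genes the median summit lay 10 bp downstream of the annotated 5′ end (quartiles -27 and 38 bp, 53 peaks), at snoRNA genes at -40 bp, upstream of it (quartiles -72 and -1 bp, 41 peaks), and at snRNA genes 92 bp downstream (quartiles 35.3 and 176 bp, 16 peaks on 11 genes). The snRNA position was not tested, and 5 second summits of the same genes enter its median, which was 78 bp without them. The hypothesis that summits lie further upstream at snoRNA than at tRNA genes was tested by permuting the class over peaks, and the difference in medians of -50 bp had a two-sided permutation p of 3.0e-05. The distances are short beside the median peak width of 430 bp.

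Within the reproducible list, peaks near snoRNA genes had a median signal of 127 against 113 for the others (permutation p = 0.00701, adjusted p = 0.0201 over 4 classes). Those near snRNA genes had 141 against 114 (permutation p = 0.0101, adjusted p = 0.0201). The 16 snRNA peaks fell on 11 genes, yet the permutation treated them as independent. A version with a single summit per gene was not run, so the snRNA p-value is likely too small.

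The top peaks held by 1 replicate alone differed in promoter share. Of the 217 top peaks that replicate 1 did not share with the top of replicate 2, 52.5% lay in promoters, and of the 211 that replicate 2 did not share, 36.0% did (Fisher's exact p = 0.00066). Of the 172 shared peaks, 50.6% lay in promoters. The snoRNA share was 16.3% of the shared peaks, 6.91% in replicate 1 alone and 4.27% in replicate 2 alone. The tRNA share was 9.88%, 16.1% and 11.8%, and the snRNA share 4.65%, 0.922% and 1.90%, in the same order. These class differences were not tested.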
